A study of Mus musculus with 80 samples.

How the data were processed

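Total RNA from the adrenal glands of 40 C57BL/6 mice, fed without restriction, was labelled radioactively and hybridised to a pair of membrane arrays per mouse (types A and B), which gave 80 arrays, per the labels' protocols. The deposited values are a score, a z-score within each array: on each array the mean over the 8448 features was 0 to within 1e-04 and the standard deviation lay between 0.9998 and 1.0002. The values were deposited to 2 decimals, none was missing, and they ranged from -8.4 to 2.81. How the images were quantified, how background was treated and on what scale the values lay before the z-transform are not given in the sources used here. Differences are therefore given in z units and never as folds, and no floor or further normalization was applied. The linear models had been planned for log-scale values and were used on the z-scores unchanged.

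Sex and age in days were taken from the sample characteristics, and the replicates of a group were numbered in the order of the numbers in the titles. The mice fell into 8 groups of 5, by sex and by age class: juvenile (17-44 days), 6-month (169-194 days), 16-month (476-499 days) and 24-month (704-743 days). The numbers in the titles fell into 5 runs, each with 1 mouse of each sex and age class. For 1 male of the 24-month class (replicate 2) the description named another mouse than the title and characteristics did, and the title and characteristics were used. Each mouse was a separate animal with 1 array of each type, so p-values measure the spread between animals together with that between hybridisations. The exception is a pair of near-identical membrane A arrays, described below, which cannot count as separate animals on that membrane. The number of arrays limits the precision.

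Feature names came from the platform annotation. Of the 16896 features on both membranes, 9663 had 1 gene symbol, 436 had several and 6797 had none, and features with several or none were counted but not named. Of the features with 1 symbol, 9641 matched a gene of the GRCm38.p6 table by their gene number, and 0 symbols changed. The 7151 named genes included 963 with features on both membranes and 1858 with more than 1 feature. A gene with more than 1 feature was represented in the list tests by the feature with the highest mean value.

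Each comparison was fitted feature by feature with limma 3.58.1 (lmFit and eBayes, R 4.3.3), separately for each membrane type. The p-values of both membranes were adjusted together by Benjamini-Hochberg, with a threshold of 0.05. Comparisons between age classes and between the sexes used 1 model with the 8 groups of all 40 mice, so that the groups shared 1 estimate of the spread. Slopes with age were fitted with sex as a covariate and are given per 100 days, and the difference of the slopes between the sexes was the product term of age and sex in the 30 adult mice. The juvenile class was also divided by age into 17-21 days and 33-44 days. All sex differences are male minus female.

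The design, the gene lists, the rule for named genes and the first set of other fits below were set before the data were examined. For each comparison the named genes were the 12 largest increases and 12 largest decreases past the threshold, up to 4 members of each list past the threshold, a fixed set of adrenal and ageing markers given whether or not they passed, and, where fewer than 5 features passed, the 5 with the smallest p. Of 31 gene lists, 26 had at least 3 measured genes and were tested in 7 comparisons with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The same tests with an estimated correlation and with fry were run beside it. Arrays were compared with each other by correlation and by the share of equal values, and array similarity was the correlation of an array with the mean of the other arrays of its type. Exact permutation tests were run for single values compared within the juvenile mice, and 1e+05 resamples were used otherwise.

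The code was tested on simulated values of all 16896 features, with the means and spread of the real features and 50 features changed at each size. The noise was drawn independently for each feature and array, without the correlation between features of the real arrays. Features of all sizes, 0.1, 0.2, 0.3 and 0.5 z units, were changed together. With fewer changed features the adjusted threshold is stricter. The shares recovered, the false calls and the list calls below hold for such values only. At a change of 0.3 z units it recovered 82% of the changed features for the sex difference in adults, 64% for juvenile against 6-month, 40% for 24-month against 6-month and 20% for the sex difference in juveniles. At 0.5 z units the shares were 94%, 88%, 94% and 58%. For the slope in adults, changes of 0.3 and 0.5 z units over the adult ages were recovered for 60% and 82% of the features. Unchanged features made up 10 of 115 calls for the sex difference in adults, 4 of 92 for juvenile against 6-month, 3 of 81 for 24-month against 6-month, 4 of 86 for the slope in adults and 3 of 42 for the sex difference in juveniles. The ribosome list, shifted by -0.1 z units, was called in each of these comparisons, with 0 of the other lists.

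The other fits were quantile normalization, centring on the median, leaving out the dimmest 25% of features, and the title-number runs as a block (the replicate block). Further ones were leaving out the mouse with conflicting labels, array weights, robust and trended moderation and fitting only the groups compared. Log2 of age, other list tests and leaving out each mouse in turn completed them. Leaving out a pair of near-identical arrays, cyclic loess, and array similarity as a covariate were added after the data were seen. No mouse was left out of the reported values. For each model result, 100 splits of the mice into groups of the same sizes were drawn.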

Results

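Gene expression in the adrenal gland was measured in 40 C57BL/6 mice to compare animals by age and sex. The mice formed 8 groups of 5: males and females that were juvenile (17-44 days), 6-month (169-194 days), 16-month (476-499 days) or 24-month (704-743 days) old. Each mouse was hybridised to a pair of membrane arrays with 16896 features in all, and every value is a z-score within its array. The median standard deviation of a feature within a group was 0.170 on membrane A and 0.155 on membrane B, against a standard deviation of 0.974 and 0.976 between the feature means. The number of arrays limits the precision of each difference.

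Several properties of the arrays bear on the comparisons. The membrane A arrays of a 733-day female (24-month class, replicate 4) and a 40-day male (juvenile class, replicate 5) held equal values at 66.0% of features and correlated at 0.999, while the next highest share of equal values in any pair was 3.52%. On membrane B the same mice correlated at 0.960, with 2.28% equal values, and which mouse the membrane A values belong to was not determined. Both arrays were kept. The arrays of males resembled the other arrays less than those of females did: the mean correlation was 0.966 ± 0.0136 in males against 0.978 ± 0.00654 in females on membrane A (SD, n = 20 each, two-sided permutation p = 0.00052) and 0.969 ± 0.00984 against 0.981 ± 0.00630 on membrane B (permutation p = 0.00011). The first principal component of the arrays followed the number in the sample title, with r = 0.567 (permutation p = 0.00015) and rho = 0.630 (permutation p = 2.0e-05) on membrane A, and r = 0.612 (permutation p = 2.0e-05) and rho = 0.641 (permutation p = 4.0e-05) on membrane B. Without the 2 mice at the ends of the numbering r was 0.581 and 0.620. Each run of title numbers held 1 mouse of each group, so the runs were balanced over sex and age class. Within each run the number rose from the juvenile to the 24-month class, so the numbering itself was not balanced over age. With sex it correlated at r = -0.026 in adults and in juveniles. Among juveniles it correlated at r = -0.273 with being 17-21 days old.

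**Figure D1:**
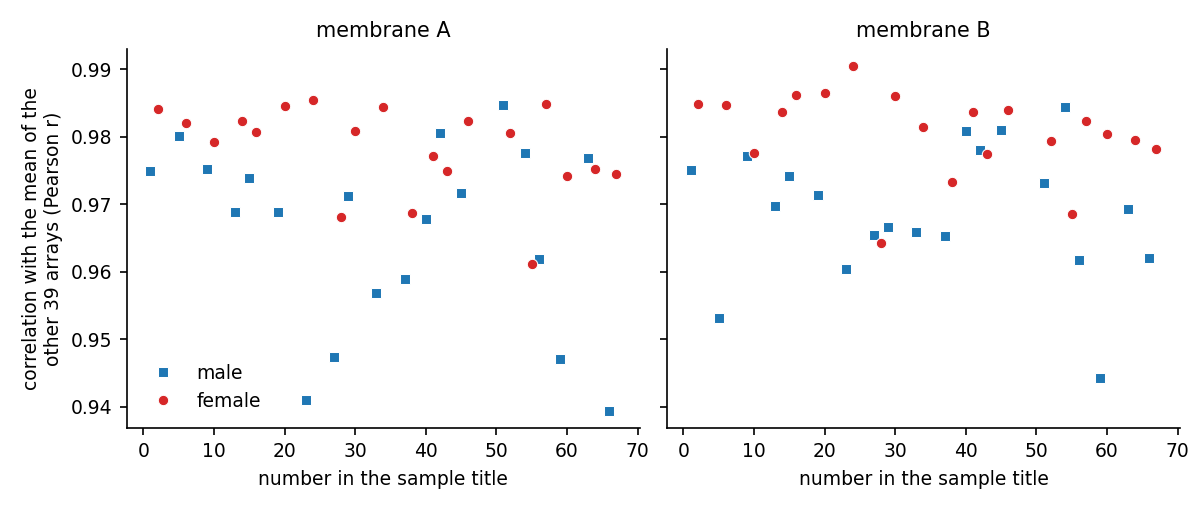
Correlation of each array with the mean of the other arrays of its membrane type (vertical axis, Pearson r) against the number in the sample title (horizontal axis), with 1 point per array and males as blue squares, females as red circles. The mean was 0.966 in males and 0.978 in females on membrane A, and 0.969 and 0.981 on membrane B.

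In juvenile mice, features of a pair of aldo-keto reductases, Akr1c19 and Akr1c14, were far higher in females than in males. Akr1c14 encodes a hydroxysteroid dehydrogenase that reduces steroid hormones. Akr1c19 stood at 0.52 ± 0.12 in juvenile females and -0.54 ± 0.07 in juvenile males (SD, n = 5 each), and the membrane B feature of Akr1c14 at 0.45 ± 0.17 and -0.38 ± 0.19. The differences were -1.06 (SE 0.111, limma adjusted p = 3.04e-07) and -0.826 (SE 0.102, limma adjusted p = 9.34e-06), and the female was above the male in 5 of 5 runs for both. Every juvenile female lay above all 35 other mice: their Akr1c19 values were 0.35 to 0.67 against at most -0.01 elsewhere, and their Akr1c14 values 0.20 to 0.69 against at most -0.09.

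The second Akr1c14 feature, on membrane A, did not show this: its juvenile difference was -0.10 (SE 0.071, limma adjusted p = 0.781). Akr1cl, the other measured member of the family, differed by -0.04 (SE 0.120, limma adjusted p = 0.963), with the female above the male in 3 of 5 runs. In the GRCm38.p6 gene table the protein-coding genes Akr1c14, Akr1c18, Akr1c13 and Akr1c19 follow each other in this order on chromosome 13. Akr1c13 and Akr1c18, a marker of the transient inner zone of the mouse cortex (the X-zone), had no named feature. Pik3c2g, the only measured member of the X-zone list, differed by -0.11 (SE 0.088, limma adjusted p = 0.818). Within the juvenile females, Akr1c19 averaged 0.45 at 17-21 days (n = 3) and 0.63 at 33-44 days (n = 2), with no test of its own. In all, 6 of 16896 features passed the threshold in juveniles, 3 higher and 3 lower in males, and the 4 others carried no single gene name. Of the 26 lists, 0 were called by camera in limma, where 1358 features had an unadjusted p under 0.05. The imprinted growth factor Igf2 stood 0.45 higher in males (SE 0.105, limma adjusted p = 0.0767), a difference that did not pass over all features. Among the imprinted growth genes Igf2 was higher when adjusted over the list alone. In the same way Mgst1 (-0.35, SE 0.089) was lower and 1 other gene higher among the antioxidant genes. A membrane B feature of Sparc (-0.25, SE 0.070) was lower among the matrix genes. The lists of chaperones, immediate early genes and erythroid cells had 1 higher gene each. The count ranged from 2 to 122 when single mice were left out and went to 176 with array weights, 29 with robust moderation and 26 without dim features, and the Akr1c19 and Akr1c14 calls were kept in each of these.

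**Figure D2:**
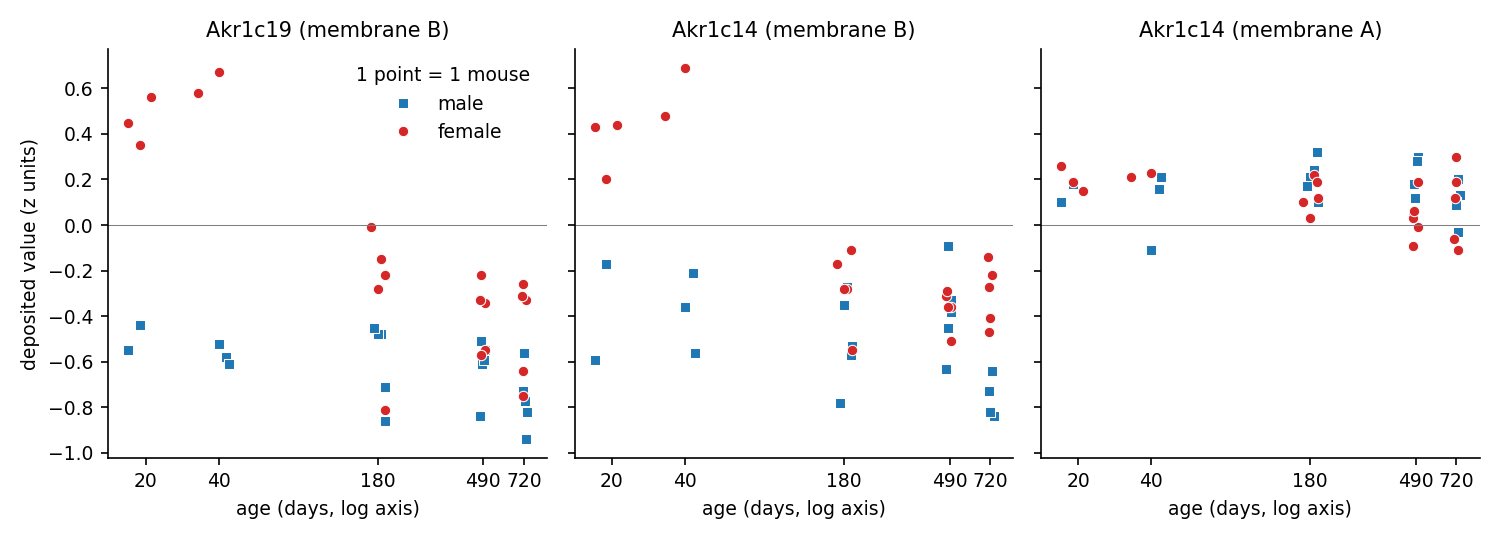
Deposited values (vertical axis, z units) of Akr1c19 and of both Akr1c14 features against age in days (horizontal log axis), with 1 point per mouse and males as blue squares, females as red circles. The 5 juvenile females lie above all other mice for both membrane B features, with values of 0.35 to 0.67 for Akr1c19 and 0.20 to 0.69 for Akr1c14, and not for the membrane A feature of Akr1c14.

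In adult mice, males and females differed at 90 of 16896 features, 20 higher and 70 lower in males (limma, 15 mice of each sex), and 50 of these carried a gene name. Mc2r, the receptor for adrenocorticotropic hormone, was lower in males and stood at -0.06 ± 0.23 in males and 0.24 ± 0.13 in females (SD, n = 15 each; difference -0.30, SE 0.059, adjusted p = 0.0226). A feature of Hsd3b1, the dehydrogenase that converts pregnenolone to progesterone, stood at 0.60 ± 0.29 and 1.05 ± 0.24 (difference -0.46, SE 0.090, adjusted p = 0.0226). The brighter Hsd3b1 feature did not differ in this way (0.01, SE 0.056, adjusted p = 0.968). Other genes lower in males were Atp6v1e1, a subunit of the proton pump of acidic organelles (-0.47, SE 0.093), the chemokine receptor Cxcr4 (-0.35, SE 0.079), the glutaredoxin Glrx5 (-0.37, SE 0.076), the formaldehyde-oxidising enzyme Adh5 (-0.38, SE 0.086), Mdn1, Wipf2, Macf1, Ccdc115, Tmem170, Actb and Spopl. Genes higher in males were Tcea1, a transcription elongation factor at the dim end of the scale (1.03, SE 0.239), Exoc5 (0.44, SE 0.103), Lrsam1 (0.35, SE 0.080), the DNA damage response gene Topbp1 (0.24, SE 0.045), the collagen Col6a2 (0.22, SE 0.047), Ppp1r8, Ppme1, Vps39 and Rimbp3. Akr1c19 was lower in adult males too (-0.28, SE 0.064, adjusted p = 0.0401), and the membrane B feature of Akr1c14 stood at -0.22 (SE 0.059, adjusted p = 0.0615), its membrane A feature at 0.08 (SE 0.041, adjusted p = 0.448).

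The sex-linked genes did not separate the adults past the threshold. Xist, transcribed from the inactive X chromosome, stood at -1.57 ± 0.50 in males and -1.13 ± 0.20 in females (SD, n = 15 each; difference -0.45, SE 0.138, limma adjusted p = 0.120), and the Y-linked Eif2s3y and Uty differed by -0.03 each (adjusted p = 0.874 and 0.958). Adjusted over the list alone, Xist was lower in males, in the direction of the labels (adjusted p = 0.0158). The Y-linked features lay below the array mean in both sexes and give no check of the labels. Xist also lay below the array mean in both sexes and did not pass over all features, so it is a weak check at most.

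Gene lists for protein synthesis and energy metabolism were lower in adult males. Of the 66 measured ribosomal protein genes 61 had lower values in males, with a median of -0.085 (camera adjusted p = 2.78e-09, adjusted p = 0.329 with an estimated correlation). Adjusted over the list alone, 6 were lower, among them Rpl36 (-0.20, SE 0.042, also past the threshold over all features), Rplp2 (-0.16, SE 0.044) and Rps18 (-0.23, SE 0.067). Of the 64 genes of oxidative phosphorylation 56 had lower values, with a median of -0.064 (camera adjusted p = 3.25e-04, adjusted p = 0.329 with an estimated correlation), and adjusted over the list alone 0 passed in limma, where 2037 of all features had an unadjusted p under 0.05. Of the 27 antioxidant and glutathione genes 21 had lower values, with a median of -0.093 (camera adjusted p = 0.0128, adjusted p = 0.329 with an estimated correlation). Adjusted over the list alone 3 of these were lower: the glutathione transferases Mgst1 (-0.21, SE 0.051, past the threshold over all features) and Gsta4 (-0.16, SE 0.050), and the superoxide dismutase Sod1 (-0.19, SE 0.056). With fry, which asks only whether the genes of a list move one way, the adjusted p was 0.0140, 0.0140 and 0.00953. In juveniles these lists were not called, but their means also lay lower in males than in females (n = 5 each). The means were 0.262 against 0.307 for the ribosome, -0.017 against 0.043 for oxidative phosphorylation and 0.165 against 0.202 for the antioxidant list. Of the 12 steroidogenesis genes 9 had lower values (median -0.06, camera adjusted p = 0.214), and adjusted over the list alone Mc2r and the steroidogenic transcription factor Nr5a1 (-0.16, SE 0.056) were lower. The arrays of males resembled the others less, as given above, and beside that the mean difference of the ribosome list went from -0.084 (SE 0.025) to -0.054 (SE 0.030) with array similarity as a covariate. The ribosome and oxidative phosphorylation lists were still called with it (camera adjusted p = 0.00291 and 0.00479), and the antioxidant list was not (0.322). With that covariate 0 of the 90 features passed (limma, 1213 at an unadjusted p under 0.05) although all 90 kept their sign and their median size went from 0.274 to 0.223. The count was also 0 without the 6-month male replicate 5, and it ranged up to 299 without other single mice and to 390 with array weights.

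**Figure D3:**
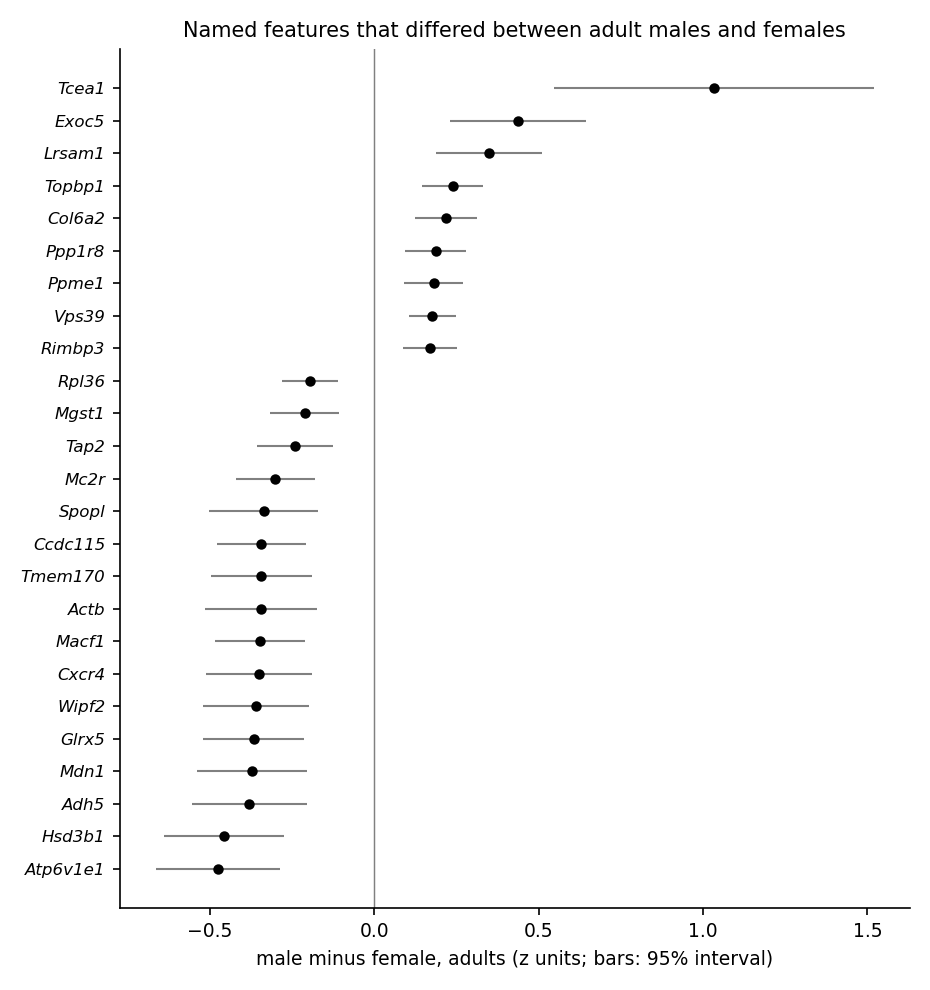
Male minus female difference in adults (horizontal axis, z units) for the features past the threshold that the rule for named genes picked. The point is at the fitted value and bars give the 95% confidence interval (15 mice of each sex). These are a part of the 50 features past the threshold with a gene name. Differences run from -0.47 for Atp6v1e1 to 1.03 for Tcea1.

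**Figure D4:**
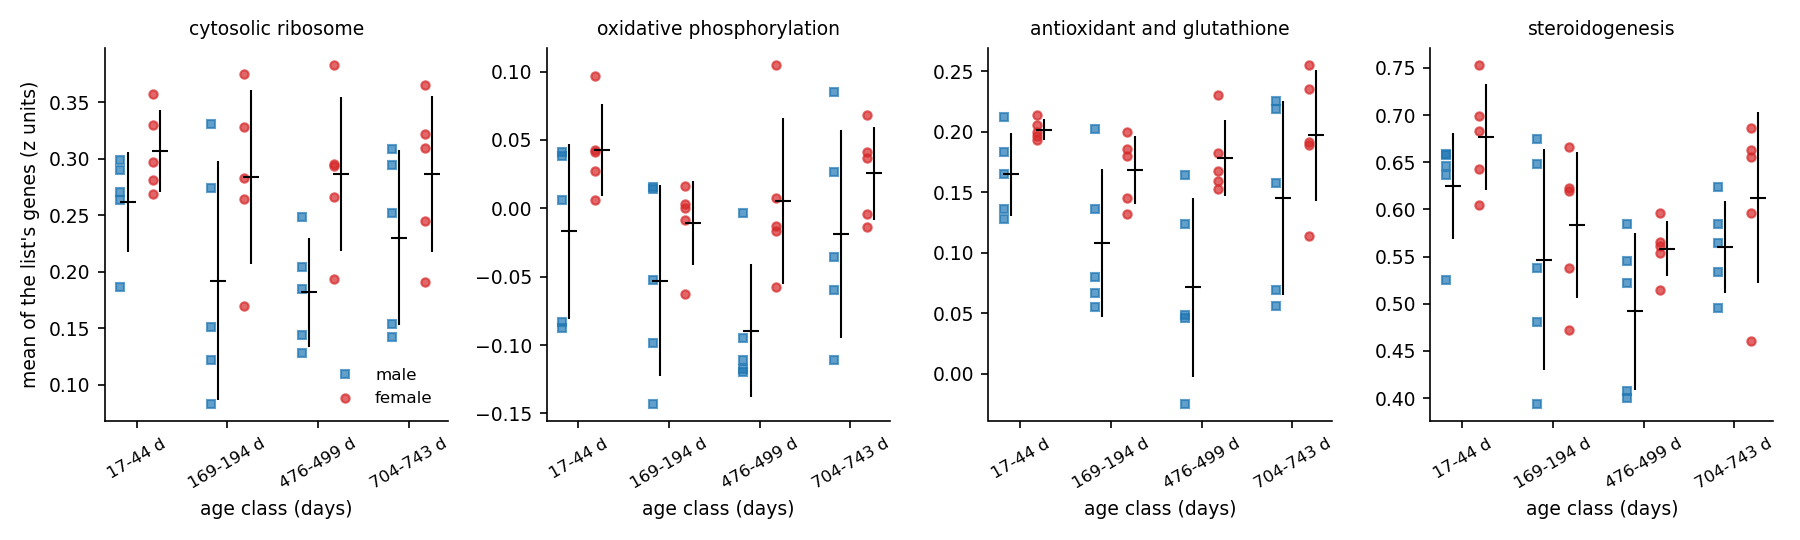
Mean of the measured genes of 4 lists (vertical axis, z units) by age class in days (horizontal axis), with 1 point per mouse, males as blue squares and females as red circles, and black bars for the mean ± SD of 5 mice. The ribosome list averaged 0.20 ± 0.08 in adult males and 0.29 ± 0.07 in adult females (SD, n = 15 each).

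The sex difference of Akr1c19 itself differed between adults and juveniles. It was smaller in adults by 0.787 z units (SE 0.128, limma adjusted p = 0.00721), and Akr1c19 was the only feature past the threshold in this test. In females Akr1c19 stood at 0.52 ± 0.12 in juveniles, -0.29 ± 0.31 at 6 months, -0.40 ± 0.15 at 16 months and -0.46 ± 0.22 at 24 months (SD, n = 5 each), and in males at -0.54 ± 0.07, -0.60 ± 0.18, -0.62 ± 0.13 and -0.76 ± 0.14. The membrane B feature of Akr1c14 moved by 0.605 in the same test (SE 0.117, adjusted p = 0.0778) and its membrane A feature by 0.179 (SE 0.081, adjusted p = 0.999). Other features with the smallest p were Glcci1 (0.38, adjusted p = 0.534), Fam76b (-0.48, adjusted p = 0.999) and Brf2 (-0.56, adjusted p = 0.999). Of the 26 lists, 0 were called by camera in limma, with 620 features at an unadjusted p under 0.05, and the ribosome list was nearest (adjusted p = 0.115). In the adipocyte list 1 gene had a higher difference when adjusted over the list alone, and 0 genes of the other lists passed.

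Between juvenile and 6-month mice, averaged over the sexes, Akr1c19 and the membrane B feature of Akr1c14 were the only features past the threshold. Akr1c19 was higher in juveniles by 0.44 (-0.01 ± 0.57 against -0.45 ± 0.29, SD, n = 10 each; SE 0.078, limma adjusted p = 0.0218) and the membrane B feature of Akr1c14 by 0.42 (0.04 ± 0.47 against -0.39 ± 0.21; SE 0.072, adjusted p = 0.0155), and the wide spread in juveniles is that between the sexes given above. By the group means, and without a test of its own, most of the difference of both features lay in the females. Juvenile and 6-month males lay much closer together. The membrane A feature of Akr1c14 differed by -0.01 (SE 0.050, limma adjusted p = 0.995). Fitted to the compared groups alone, neither call was kept (adjusted p = 0.177 for both), and over 11 other fits the adjusted p ranged from 0.00628 to 0.177 for Akr1c19 and from 0.00422 to 0.177 for Akr1c14. A membrane A feature of the matrix protein gene Sparc stood 0.34 higher in juveniles (SE 0.079, limma adjusted p = 0.571). Sltm stood at -0.19 (SE 0.047) and the kinesin Kif4 at -0.69 (SE 0.178, adjusted p = 0.951 for both). The markers of proliferation and growth did not pass: Mki67 differed by 0.07 (SE 0.085), Top2a by -0.06 (SE 0.059), Igf2 by -0.03 (SE 0.074), H19 by -0.07 (SE 0.083) and Dlk1 by 0.02 (SE 0.063). Of 42 cell cycle genes 24 had higher values in juveniles (camera adjusted p = 0.871), as did 7 of 12 imprinted growth genes (adjusted p = 0.906).

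Genes of steroid synthesis, the ribosome and oxidative phosphorylation lay slightly higher in juveniles than at 6 months. Of the 12 steroidogenesis genes 11 had higher values, with a median of 0.089 (camera adjusted p = 0.00636, adjusted p = 0.218 with an estimated correlation). Its members included Nr5a1 (0.14, SE 0.069), Cyp11a1, which cleaves the cholesterol side chain (0.11, SE 0.048), the cholesterol transporter Star (0.18, SE 0.132), Scarb1 (0.12, SE 0.112) and Hsd3b1 (0.02, SE 0.068), and 0 passed when adjusted over the list alone (limma, 861 of all features at an unadjusted p under 0.05). Of the 66 ribosomal protein genes 51 had higher values, with a median of 0.037 (camera adjusted p = 0.00362, adjusted p = 0.819 with an estimated correlation), and of the 64 genes of oxidative phosphorylation 48 did, with a median of 0.037 (adjusted p = 0.0110, adjusted p = 0.819 with an estimated correlation). With fry the adjusted p was 0.118 for steroidogenesis, 0.640 for the ribosome and 0.421 for oxidative phosphorylation, so none of the 3 lists was called by it. Adjusted over the list alone 0 of either passed, and 1 macrophage gene was higher. The counts of called features and lists fell to 0 and 1 without the 6-month male replicate 2, and to 0 features without the juvenile male replicate 3 or the juvenile female replicate 4.

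Ageing in adults changed no feature past the threshold when all mice were kept. From 6 to 24 months 0 features passed (limma, 1183 at an unadjusted p under 0.05), from 6 to 16 months 0 passed (605) and along the slope with age in adults 0 passed (962). Over all 40 mice the slope gave 0 (1754), where 844.8 would be at that level by chance in each comparison. The smallest p between 24 and 6 months belonged to the signalling gene Wnt6, at 0.51 ± 0.12 against 0.27 ± 0.12 (SD, n = 10 each; difference 0.24, SE 0.049, limma adjusted p = 0.376), followed by Trnt1 (0.28, SE 0.067), Thumpd1 (0.34, SE 0.079), Arhgap1 (0.64, SE 0.154) and the collagen-processing protease Bmp1 (0.33, SE 0.082), with an adjusted p of 0.468 for each. Over 11 other fits the adjusted p ranged from 0.0277 to 0.579 for Wnt6 and from 0.0277 to 0.623 for Trnt1, each past the threshold in 1 of them. That fit left out the near-identical pair of arrays and also took the title-number runs as a block, and 9 features passed in it, while 0 passed with either change alone. In the adult slope Wnt6 stood at 0.04 per 100 days (SE 0.0082, adjusted p = 0.165), before Trnt1, Psmc3, Arhgap1 and Wdr91. Between 16 and 6 months Gng13, Srm, Abcc3, Fbxo11 and Dnajc10 had the smallest p, with an adjusted p of 1 for each. In the slope over all mice these were Akr1c19 (-0.07 per 100 days, SE 0.015, limma adjusted p = 0.216), the membrane B feature of Akr1c14, Cdh16, Sparc (a membrane B feature) and Anxa7.

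No measured fixed marker of adrenal cell types passed the threshold between 6 and 24 months. Cyp21a1, Cyp11b1, Cyp11b2, Akr1c18, Dbh, Pnmt, Chga and Npy had no named feature and were not tested. Of the steroidogenesis list 12 of 26 genes were measured, and of the chromaffin cell list 8 of 34. Pik3c2g differed by -0.10 (SE 0.062), Scarb1 by 0.14 (SE 0.112), Hsd3b1 by 0.08 (SE 0.068) and the Schwann cell gene Pmp22 by -0.38 (SE 0.203). Star differed by -0.05 (SE 0.132), Cyp11a1 by -0.02 (SE 0.048), the medullary enzyme gene Th by 0.04 (SE 0.063), Col1a1 by 0.02 (SE 0.056), Col3a1 by 0.02 (SE 0.074), and the myeloid markers Lyz2 and Cd74 by -0.01 (SE 0.080) and 0.00 (SE 0.073). Of the 26 lists, 0 were called by camera in limma between 24 and 6 months or along the adult slope. Of 33 collagen and matrix genes 24 had higher values at 24 months (median 0.039, adjusted p = 0.571), of 42 cell cycle genes 29 did (median 0.035, adjusted p = 0.571), and of 13 genes of macrophages and antigen presentation 6 did (median -0.012, adjusted p = 0.944). Adjusted over the list alone 0 genes passed in these 3 lists, and 1 of 40 proteasome genes was higher. In the simulated values, drawn without correlation between features, 94% of changes of 0.5 z units were recovered in this comparison. For changes of 0.3 z units the share was 40%, so smaller changes with age would mostly be missed even there. Changes of 0.1 to 0.5 z units were made there at once, in 50 features of each size. With fewer changed features the adjusted threshold is stricter and these shares would tend to be lower, so larger changes may be missed too.

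Males and females did not differ past the threshold in their slope with age (0 features, limma, 681 at an unadjusted p under 0.05). The smallest p belonged to a feature of the glutathione transferase Gstm1, with a slope of -0.05 per 100 days in males (SE 0.023) and 0.10 in females (SE 0.017, n = 15 each; difference -0.15, SE 0.028, adjusted p = 0.158). The others were Nat10, Msantd4, Pold3 and Nadk2, with an adjusted p of 0.999 each.

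Among the juveniles, haemoglobin features lay lower at 33-44 days than at 17-21 days, without passing the threshold. All 21 features of 4 globin genes had lower values in the older mice (median -0.388, from -0.587 to -0.124), 17 of them with an unadjusted p under 0.05 and 0 past the threshold (limma, smallest adjusted p = 0.384). The features repeat a few related genes in the same mice, so these counts are not independent findings. The mean of these features was 0.15 ± 0.10 at 33-44 days and 0.43 ± 0.33 at 17-21 days (SD, n = 5 each). The 17-day male (replicate 4) stood highest at 1.01, and without that mouse the difference, taken within each sex and averaged, went from -0.342 (SE 0.101) to -0.193 (SE 0.102). The centromere gene Cenpi had the smallest p (-0.48, SE 0.091, adjusted p = 0.143), followed by Hba-a2 (-0.53, SE 0.114), 1810064F22Rik (0.33, SE 0.078), Phtf1 (-0.62, SE 0.150) and Ube2a (0.92, SE 0.230). With array weights 5 features passed, among them Cenpi (adjusted p = 0.0135) and Hba-a2 (adjusted p = 0.0315). Over 10 other fits the adjusted p ranged from 0.0135 to 0.151 for Cenpi, past the threshold in 3, and from 0.0315 to 0.650 for Hba-a2, past it in 2. In the fit reported here 0 features passed (limma, 921 at an unadjusted p under 0.05) and 0 of the 26 lists were called. An erythroid and an endothelial gene were lower when adjusted over the list alone (1 gene each). Without the juvenile male replicate 4 the count was 19, and without the juvenile male replicate 3 it was 7.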

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

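The tests of array similarity and related transcripts for Akr1c19 and Akr1c14, that of array similarity for the gene lists, and that of red blood cells were chosen, or their bounds changed, only after the results were seen. A sample stood apart from the others of its group in 5 of 62 groups tested, where chance marks about 1 in 20. A group was 1 sex of an age class, a whole age class of both sexes or an age part of the juveniles. On membrane A the 6-month female replicate 5 had an array similarity of 0.974, against 0.982 to 0.985 in the others. Arhgap1 was at -0.49 in the 24-month female replicate 2, against -1.43 to -0.94 in the other 24-month mice of both sexes. At 17-21 days the male replicate 4 had Cenpi at 0.53 against -0.13 to 0.05 and Phtf1 at 1.1 against 0.07 to 0.30, and the male replicate 3 had Ube2a at -2.94 against -1.16 to -0.88. The male minus female difference of Akr1c19 was less negative in adults than in juveniles by 0.787, by the test of the difference itself.

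Other splits of the same mice, 100 for each result with the real one included, were used to ask whether chance gives as much. For the 2 features between juvenile and 6-month mice, 1 of 100 splits gave as many (highest other 1). For the 6 features between the juvenile sexes 2 did (highest other 10), and for the 90 features between the adult sexes 2 did (highest other 2168). Few splits did so for these 3, without correction for the number of results split in this way. Chance is thus made less likely for them and is not excluded. For the 1 feature whose sex difference differed between adults and juveniles 8 splits gave as many (highest other 1242), so chance was not excluded. With a real count of 0, all 100 splits gave as many for the slope in all mice (highest other 1), the slope in adults (1888), 16-month against 6-month (4), 24-month against 6-month (148), the sex difference in slope (1) and 33-44 against 17-21 days (1). For gene lists, 2 splits gave as many as the 3 called between juvenile and 6-month mice. For the adult sexes 4 gave as many as the 3 called (highest other 3 in both). These shares were not corrected for the number of results either, and 0 lists were called with an estimated correlation, so chance was not excluded for both. With 0 lists called, all 100 splits gave as many for the slope in adults (highest other 3), 24-month against 6-month (2), the juvenile sexes (2), adults against juveniles (4) and 33-44 against 17-21 days (2). At an unadjusted p under 0.05, 7 splits gave as many features as the 1754 of the slope in all mice (highest other 3287), 21 as many as the 962 of the slope in adults (4860), 26 as many as the 1183 of 24-month against 6-month (3709) and 10 as many as the 2037 of the adult sexes (4725), so chance was not excluded for these. Splits with several times the real count point to a structure of the samples beside sex and age.

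Akr1c19 and the membrane B feature of Akr1c14 were higher in all 5 juvenile females than in any other mouse. Array similarity was argued against as the whole cause: the juvenile difference of Akr1c19 was -1.06 (SE 0.111) before and -1.04 (SE 0.121) with similarity as a covariate, and that of Akr1c14 was -0.826 (SE 0.102) and -0.806 (SE 0.111). The membrane A feature of Akr1c14 did not follow, with a gap of 0.726 (SE 0.124) between the 2 features, which is what signal from a related transcript at 1 of them would give. Akr1c18 and Akr1c13 lie between both genes in the GRCm38.p6 table and had no named feature, so the transcript measured by these features may be a neighbour's and stays open. That leaves open which gene was measured. The difference by sex was called in the juveniles and, for Akr1c19, its change between adults and juveniles was called too. For that change 8 of 100 splits gave as many features, so chance was not excluded by them. What in the sex or age of the mice gives the pattern stays open, as untested.

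The ribosome, oxidative phosphorylation and antioxidant lists were lower in adult males. A shift shared by all genes of that brightness was argued against, because 0, 0 and 1 of 10000 random lists of the same size and brightness had a mean difference as low. The random lists averaged -0.017, -0.013 and -0.013. Their genes were drawn singly, without the correlation within a list, and the lists tested had been called in the same data. The shares of random lists thus overstate the strength of this argument. Array similarity, which was lower in males, stays open. With it as a covariate the differences went from -0.084 to -0.054 (SE 0.030), from -0.060 to -0.053 (SE 0.025) and from -0.073 to -0.049 (SE 0.022). The ribosome and oxidative phosphorylation lists were still called at the preset correlation (camera adjusted p = 0.00291 and 0.00479). The antioxidant list was no longer called (camera adjusted p = 0.322, with 0.00585 to 0.329 over 10 other fits). RNA or hybridisation quality that differs between the sexes may thus account for part of it, and cannot be told apart from sex, because similarity and sex go together in these arrays. Sex itself stays open, as untested.

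The 21 globin features lay lower at 33-44 days than at 17-21 days. Drift along the title numbers and array similarity were argued against, since the difference was -0.342 (SE 0.101) before, -0.347 (SE 0.104) with the title number and -0.305 (SE 0.088) with similarity. More red blood cells in the younger glands could give this. The erythroid list was lower with an exact one-sided permutation p = 0.04, ages exchanged within sex. The exact two-sided permutation p was 0.06 when compared within sex or 0.30 when pooled over the sexes, the form run first. The list holds the globins Hba-a1 and Hba-a2 among its 5 genes, so it gives no separate support for red blood cells. Its members that are not globins did not follow (Alas2 -0.11, Slc4a1 0.04, Car2 0.09, exact one-sided p = 0.20, 0.69 and 0.99), and this condition was added after the values were seen, so blood content cannot be told apart from globin transcripts alone with 5 mice of each age. The 17-day male replicate 4 carries much of the difference, which was -0.193 (SE 0.102) without it, and age stays open, as untested.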

How the results depend on the processing

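Leaving out the near-identical pair of arrays, alone or with the block, cyclic loess and array similarity were chosen after seeing the data. Reversal was checked only for the values picked by the rule for named genes, and not for the other calls. No call among these reversed under any alternative, and 58 of 267 such values changed sign in at least 1 (0 of them called, adjusted p at least 0.474). The causes of the moves were not tested unless given. The sex difference in adults went from 90 features to 209 without dim features (fewer tested), 212 with the replicate block, 229 without the mouse with conflicting labels, 390 with array weights, 182 with robust and trended moderation, 46 with only the groups compared (fewer samples), 269 without the pair and with the block, 55 with cyclic loess and 0 with array similarity (1213 at an unadjusted p under 0.05). The share higher in males was 22.2%, and 21.9%, 26.7% and 29.1% with quantile normalization, median centring and loess. The sex difference in juveniles went from 6 to 26 without dim features, 13 with the replicate block, 176 with array weights, 29 with robust moderation, 12 with only the groups compared and 2 with similarity. Juvenile against 6-month went from 2 to 1 with array weights and 0 with only the groups compared. The age slope in all mice went from 0 to 2 with array weights, 2 with log2 age and 4 without the pair and with the block (among them Fen1, Trnt1 and Tex19.1), and 24-month against 6-month to 9 with the latter (among them Wnt6, Trnt1, Psmc3 and Cxcr4). Adults against juveniles went from 1 to 2 with quantile normalization, median centring, no dim features or loess. The sex difference in age slope of adults went from 0 to 1 without dim features, and 33-44 d against 17-21 d to 1 with the block (Cenpi), 5 with array weights and 2 without the pair and with the block (Cenpi and Hba-a2). Gene list tests called 0 with an estimated correlation for the adult sexes and for juvenile against 6-month (also 0 with fry, directional or mixed), and 1 with the mean of a gene's features for the juvenile sexes. The labels do not say what the title-number runs share. Deviations of 56 (A) and 54 (B) of 140 pairs of mice in a run correlated over 0.1, so not every pair deviated together, while the mean r was 0.061 and 0.076 within runs and -0.044 and -0.047 between them. The replicate block changed no other count by over 1.5 times. Of 30 calls picked by the rule for named genes, 30 were kept with the block, 27 with quantile normalization, 26 with median centring and 16 with only the groups compared. Of the 27 such calls between the sexes 2 were kept with similarity.

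With each mouse left out in turn, the adult sex count was 0 without the 169-194 d male replicate 5. It was 13 to 22 without 169-194 d females 1 and 4 and male 2, 476-499 d males 2, 3 and 5 and females 2, 3 and 5, and 704-743 d males 1 and 5 and females 3 and 4. It was 46 to 60 without juvenile females 2 to 5 and male 3, 169-194 d female 3, 476-499 d females 1 and 4, and 704-743 d female 1 and male 4, and 167 to 299 without 169-194 d males 1, 3 and 4, 476-499 d male 4, and 704-743 d males 2 and 3, and 61 to 131 without the others. The juvenile sex count ranged from 2 (juvenile males 1, 3 and 5, females 3 and 4) over 3 (male 2, female 2) to 17 (male 4), 29 (169-194 d female 1), 39 (704-743 d male 3) and 122 (juvenile female 1). Juvenile against 6-month was 0 without 169-194 d male 2, juvenile male 3 or female 4, 1 without juvenile females 3 and 5, juvenile male 5 or 169-194 d male 3, and 4 without 169-194 d male 1. Its lists ranged from 1 (169-194 d male 2) to 3. For 33-44 d against 17-21 d the range was 0 to 19 (7 without juvenile male 3, 19 without male 4), for adults against juveniles 1 to 2 (2 without juvenile female 2 or male 3, 476-499 d male 2 or 169-194 d male 5), for the slope in all mice 0 to 1 (169-194 d female 3) and for the sex difference in slope 0 to 1 (169-194 d female 2 or male 3, 704-743 d male 3). Lists for adults against juveniles ranged from 0 to 1 over 8 such mice. Adult sex lists stayed at 3, and the slope in adults, 16-month and 24-month against 6-month and all other lists at 0 features or lists by limma. Signal over background is not given for these arrays.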

Other observations

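The test of Gstm features was chosen after the result of Gstm1 was seen and before the other Gstm features were looked at. Among adults, the collagen and matrix list held genes that differed between the sexes in both directions. Of its 33 measured genes 24 had lower and 9 higher values in males, with a median of -0.05 and no call by camera (adjusted p = 0.678), while fry's test for change in either direction gave an adjusted p of 0.00399. Adjusted over the list alone 5 passed, 3 higher and 2 lower in males, and Col6a2, a beaded-filament collagen, was the only one past the threshold over all features. Lists for tissue that could be carried along with the gland gave no call between the adult sexes (camera, kidney adjusted p = 0.759, adipocytes 0.678, muscle and liver 0.928). Few of their genes were measured (5 of 16, 3 of 20 and 5 of 16), so carried-along tissue is not excluded by this. With array similarity as a covariate 0 features passed in the comparison of the adult sexes. Chromaffin cell genes were not called either (4 of 8 lower, adjusted p = 0.682), nor was Tap2's list, MHC class I and interferon (9 of 12 lower, adjusted p = 0.301), though Tap2, a peptide transporter of antigen presentation, was itself lower in males (-0.24, SE 0.057, adjusted p = 0.0434).

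The difference between males and females in the slope of Gstm1 with age was -0.15 per 100 days at 1 feature and did not pass the threshold (SE 0.028, limma adjusted p = 0.158). The hypothesis that all mu-class glutathione transferases follow was tested on the 7 other measured Gstm features, of which 0 had a slope difference of the same sign at an unadjusted p under 0.05 in limma. The other features of Gstm1 gave 0.0055 (SE 0.025) and -0.016 (SE 0.037), which argues against the hypothesis.

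For the near-identical membrane A arrays, each mouse's position on the first 3 components of membrane A was predicted from its own membrane B array. The distance was 2.03 for the 733-day female and 1.26 for the 40-day male, against 0.353 to 7.25 (median 1.46) for the 38 other mice, and neither array could be assigned by it.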
